A study of Rhodotorula mucilaginosa with 2 samples.

How the data were processed

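RNA-seq libraries of 2 Rhodotorula mucilaginosa samples were analysed, 1 labelled as induced by patulin before culture in broth and 1 as cultured in broth only, each with its own table of the same 9201 assembled genes. Per the labels, total RNA was extracted with a fungal RNA kit after grinding in liquid nitrogen, and libraries followed standard Illumina protocols. Whether the libraries were stranded or made by poly(A) selection is not given in the sources used here. The gene identifiers carry the prefix that the de novo transcriptome assembler Trinity writes, and the column layout, per the file headers, is that of gene-level output of the quantification program RSEM. Per the submitters' processing notes, HTSeq 0.6.1 was among the tools, with no role stated, and HTSeq does not write tables of this layout. The versions and settings of assembly, alignment and quantification are not given in the sources used here.

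The expected counts deposited by the authors are estimated counts per assembled gene, in which a read that matches several transcripts is divided between them. They were not normalized and summed to 10568012 in the control and 8222785 in the patulin library. They were not whole (beyond a tolerance of 0.004) for 27.3% of the genes in the control and 26.5% in the patulin library. The deposited TPM values are scaled by effective length, per the file headers, and sum to 1000000 in each library. The deposited FPKM values are per kilobase of effective length and relative to the sum of the same estimated counts, since they imply totals of 10567998 and 8222792. The length and effective length columns deposited by the authors are in bases, and for genes over 2000 bases they differed by 253.92 in the control and 256.15 in the patulin library, so fragments had nearly the same length in both.

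Expected counts were rounded to whole numbers, so an estimated count under 0.5 counts as 0. Libraries were scaled by the median of the ratios of the counts of genes above 0 in both, which gave a patulin over control factor of 0.704, against a ratio of totals of 0.778. The log2 ratio of scaled counts was taken with a pseudocount of 0.5. Genes with at least 10 counts in either library were considered, which left out 1699 genes. For each gene an exact (Clopper-Pearson) 95% interval of the share of its counts that lie in the patulin library was converted to an interval of the log2 ratio. A gene was counted as higher or lower where this interval lay wholly beyond 2-fold. The interval treats estimated counts as independent reads. It therefore leaves out the uncertainty of dividing reads between similar transcripts, PCR duplicates, and all variation between cultures. With 1 library per group no test of the condition was made and no p-value is given. Against a library at 0, a bound was computed with that library set to 3 counts.

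The counting procedure was tested on simulated data for the comparison of patulin with control, with Poisson counts for the 9201 genes drawn from the observed means. Changes were planted only in genes whose mean count was above the minimum of the rule. The recovery rates therefore do not cover the considered genes of lowest count. Of 50 genes simulated 8-fold higher, 100% were recovered, and of 50 simulated 4-fold higher, 96% were. Of 50 genes at a ratio of 0.25, 88% were recovered, and of 50 at a ratio of 0.125, 98% were. No call was made among 7205 unchanged genes, and 95.4% of the intervals held the simulated ratio. The simulation held counting error only. It could not show false calls from the division of reads between similar transcripts or from variation between cultures.

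The rule for named genes was fixed before the data were examined. It named, per direction, the genes whose interval bound nearest to 0 was farthest from 0, limited to 2 identifiers per direction where identifiers have no gene names. A set of 29 gene lists (among them glutathione metabolism, short-chain dehydrogenases, transporters, chaperones and ribosomal proteins) was also fixed then, to be matched on gene names. The tables pair the identifiers with no names, and 0 identifiers were matched, so no list was analysed. Members of one component were taken as the genes whose identifiers agree up to the gene number, and a read cluster as those that agree up to the component number. The alternatives planned were scaling by total counts or by edgeR TMM factors, a minimum of 1 or 50 counts, a pseudocount of 5 counts, the deposited TPM and FPKM, a ratio of at least 2-fold without an interval, and a 4-fold rule. Sums over components and read clusters, genes alone in their component, genes with whole estimated counts, and size factors from genes with a mean scaled count of at least 100 were added after the data were examined. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and R 4.3.3 with edgeR 4.0.16, which was used for TMM factors only. Figures were drawn with matplotlib 3.10.9.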

Results

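RNA of the carotenoid-forming basidiomycete yeast Rhodotorula mucilaginosa was sequenced in 1 library from yeast that had been induced by patulin and afterwards cultured in nutrient yeast dextrose broth, and in 1 library from yeast cultured in the same broth without induction. Patulin is a lactone mycotoxin made by moulds such as Penicillium expansum on apples and other fruit. Both cultures were described with an age of 15 hours and were shaken at 180 rpm and 28°C. The labels do not give the dose and length of the patulin exposure, whether patulin was present in the broth, the strain, or whether RNA of several cultures was pooled. A number in the title of the control is unexplained, so a further difference between the cultures is not excluded. Estimated counts were analysed for 9201 assembled genes, which hold 10071 transcripts. They summed to 10568012 in the control library and 8222785 in the patulin library, so the control was 1.29 times deeper. The genes carry de novo assembly identifiers without gene names. The groups described here are therefore groups of assembled genes, set by abundance, by size of change and by place in the assembly, and no function is assigned to any of them. With 1 library per group the difference between the libraries has no replicate check. Intervals cover counting error only.

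The libraries shared most of their expressed genes. In the control, 8463 genes had at least 1 TPM and 5629 had at least 10 TPM. The corresponding numbers in the patulin library were 8262 and 5515. Across the 9201 genes, Pearson's r of log2(TPM + 1) between the libraries was 0.94 and Spearman's rho of TPM was 0.943, where genes are not independent replicates. An estimated count under 0.5 was found for 388 genes in the control and for 561 in the patulin library, of which 185 were the same genes. A count of 0 allows up to 3 counts, which is 2.84e-05% of the control library and 3.65e-05% of the patulin library.

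The most abundant transcript by count was the same assembled gene in both libraries, and it took a larger share of the patulin library. This gene of 6334 bases held 5.91% of the counts in the control (exact 95% binomial interval 5.89% to 5.92%) and 14.3% in the patulin library (14.25% to 14.30%). Its level was 11319 TPM in the control and 29384 TPM in the patulin library. After scaling it was 2.67-fold higher in the patulin library, a log2 ratio of 1.42 (counting interval 1.41 to 1.42). By TPM the ratio was 2.6. The 10 genes with the most counts held 13.2% of the control counts and 19.7% of the patulin counts. The leading 50 genes by count held 27.3% of the control counts and 31.7% of the patulin counts. By TPM, the leading 50 genes held similar shares, 35.2% in the control and 34.2% in the patulin library.

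The comparison of the patulin library with the control asks which transcripts differ between the induced and the uninduced yeast. Of 7502 genes with at least 10 counts in either library, 295 were higher in the patulin library and 258 were lower, by the rule that the 95% counting interval lies wholly beyond 2-fold. Together they were 7.37% of the genes considered. Most genes were near the centre: 86.0% had a ratio within 2-fold, and the middle part of the distribution, between the 25th and 75th percentiles, ran from a log2 ratio of -0.3 to 0.27. Beyond 4-fold, 120 genes were higher and 100 were lower. Beyond 16-fold, 46 were higher and 24 were lower, of which 8 and 4 were alone in their component. The rule is not symmetric at these depths. At equal scaled levels, a count of 0 in the deeper control puts the interval farther from 0 than a count of 0 in the patulin library. In the simulation, 96% of 4-fold increases and 88% of 4-fold decreases were recovered. By deposited TPM with a pseudocount of 1 and no interval, 559 genes were at least 2-fold higher and 776 at least 2-fold lower, and with the interval rule and scaling by total counts 250 were higher and 309 lower. The balance between the directions therefore turned with the criterion, and also with scaling by total counts alone. It did not turn with scaling by TMM factors, which gave 290 higher and 261 lower. The total counts include the most abundant gene, which held 5.91% of the control counts and 14.3% of the patulin counts.

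The counts of higher and lower genes depended on whether a gene was alone in its assembly component. A component is a set of transcripts that the assembler built from one connected graph of overlapping reads, so its members can share sequence. How much they share was not examined here. Of the 4526 considered genes that were alone in their component, 119 (2.63%) were higher and 84 (1.86%) were lower. Of the 2976 considered genes that shared a component, 176 (5.91%) were higher and 174 (5.85%) were lower. Genes with an estimated count under 0.5 in one library were concentrated among the sharing genes. There were 77 such genes among the 176 higher ones and 79 among the 174 lower ones, against 4 and 4 among the genes that were alone. When counts were summed over components, a choice made after the data were examined, the same interval rule gave these numbers: 145 components were higher and 107 were lower. These include the 119 higher and 84 lower genes that were alone, whose component sum is the gene itself. Of the 176 higher sharing genes, 39 belonged to a component whose sum was also higher by the interval rule, and of the 174 lower ones 32 belonged to a component whose sum was also lower.

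**Figure D1:**
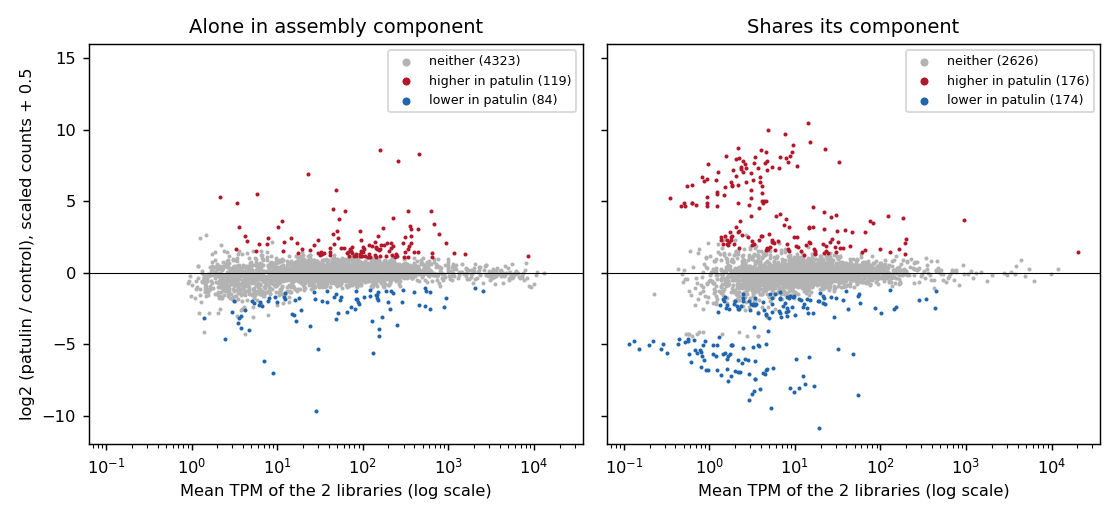
Each point is one of the 7502 considered genes, with its mean TPM over both libraries on a log scale (x axis) and the log2 ratio of scaled counts, patulin over control, with 0.5 added (y axis). Red points are higher and blue points lower by the counting interval rule, 119 and 84 among genes alone in their component (left) and 176 and 174 among genes that share one (right), where 2 separate bands of extreme ratios appear at low abundance. For genes with an estimated count under 0.5 in one library, the plotted ratio is set by the added 0.5 and is not a measured one.

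Among genes alone in their component, the largest increases involved transcripts that were rare in the control and abundant in the patulin library. TRINITY_DN5397_c1_g1, of 1473 bases, had 32 counts (2.89 TPM) in the control and 7273 counts (909 TPM) in the patulin library. Its scaled level was 317-fold higher, a log2 ratio of 8.31 (counting interval 7.84 to 8.88). A gene of 1615 bases had 10 counts in the control and 2849 in the patulin library, a log2 ratio of 8.58 (7.78 to 9.72). A gene of 2027 bases had 38 and 6072 counts, a log2 ratio of 7.80 (7.37 to 8.33). A gene of 2011 bases was already expressed in the control at 60.6 TPM and stood at 1189 TPM in the patulin library, a log2 ratio of 4.33 (4.24 to 4.43). The lengths and values of the last 3 genes, like those of the unnamed genes that follow, were chosen after their values were seen. The 28 genes of this kind that were higher beyond 4-fold summed to 1249 TPM in the control and 11980 TPM in the patulin library.

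Decreases of more than 4-fold among genes alone in their component were of similar number. The 26 genes that were lower beyond 4-fold summed to 7216 TPM in the control and 1052 TPM in the patulin library. A gene of 1181 bases had 480 counts (57.1 TPM) in the control and none in the patulin library, at least 113-fold lower with the patulin library set to 3 counts. A gene of 447 bases had 455 and 6 counts, a log2 ratio of -5.64 (-7.19 to -4.61). A gene of 2412 bases was at 300.21 TPM in the control and 13.2 TPM in the patulin library, a log2 ratio of -4.47 (-4.69 to -4.26). A gene of 828 bases was at 293 and 18.6 TPM, a log2 ratio of -3.93 (-4.31 to -3.59). Beyond 16-fold, 8 genes of this kind were higher and 4 were lower.

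The named genes that share a component each had another member of nearly equal length in it. TRINITY_DN22_c0_g1, of 3407 bases, had an estimated count of 0.36 in the control and 583 in the patulin library, at least 276-fold higher with the control set to 3 counts. TRINITY_DN22_c0_g2, of 3406 bases, had 1094 counts in the control and 0.01 in the patulin library, at least 257-fold lower with the patulin library set to 3 counts. These bounds allow for counting error only, and not for how reads were divided between the 2 genes. Both genes are the only members of one component, and their summed count was 1094 in the control and 583 in the patulin library, a log2 ratio of -0.40 (-0.55 to -0.26). TRINITY_DN4764_c0_g2, of 1012 bases, had 756 counts in the control and 1 in the patulin library, a log2 ratio of -8.55 (-14.4 to -6.57). The other member of its component, of 1011 bases, had 22104 and 13711 counts, and the component's sum had a log2 ratio of -0.23 (-0.26 to -0.20). In all, 164 genes that passed the 2-fold rule had an estimated count under 0.5 in one library, 81 of them in the control and 83 in the patulin library. Of these, 156 shared a component, and the point ratio of the component's sum was within 2-fold for 143 of the 156. For 6 of the other 13, its counting interval lay wholly beyond 2-fold.

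**Figure D2:**
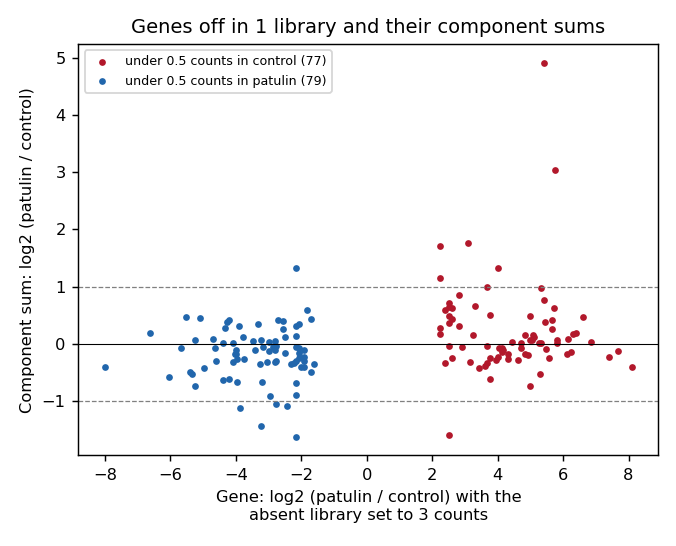
Each point is one of the 156 genes that share a component and have an estimated count under 0.5 in the control (red, 77) or in the patulin library (blue, 79). The x axis gives the gene's log2 ratio with the empty library set to 3 counts and the y axis the log2 ratio of its component's summed counts; 143 points lie between the dashed lines at 2-fold.

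The direction of change varied with abundance. Among the 1090 considered genes with a mean of 100 to 1000 TPM, 65 were higher and 38 lower, the median log2 ratio was 0.13, and 691 had a ratio above 0. Among the 146 genes of at least 1000 TPM, 4 were higher and 2 lower, the median was -0.07 and 88 had a ratio below 0. Among the 1921 genes under 10 TPM, 131 were higher and 150 lower, the median was -0.26 and 1224 had a ratio below 0. The minimum of 10 counts applies to unscaled counts, so rare genes passed it more easily through the deeper control. This can lower the median of the lowest class. The middle class of 10 to 100 TPM, with 4345 genes, had a median of 0.02, with 95 genes higher and 68 lower. Genes alone in their component gave medians of 0.14 (928 genes), -0.07 (127 genes), -0.33 (659 genes) and 0.03 (2812 genes) in the same 4 classes. Scaling by total counts moved the median of all considered genes from 0 to -0.144. It moved the medians of the classes of 10 to 100 TPM and of 100 to 1000 TPM to -0.12 and -0.012. Their sign, unlike that of the lowest and highest classes, therefore turned with scaling by total counts. Scaling by TMM factors moved the median of all considered genes to -0.013.

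**Figure D3:**
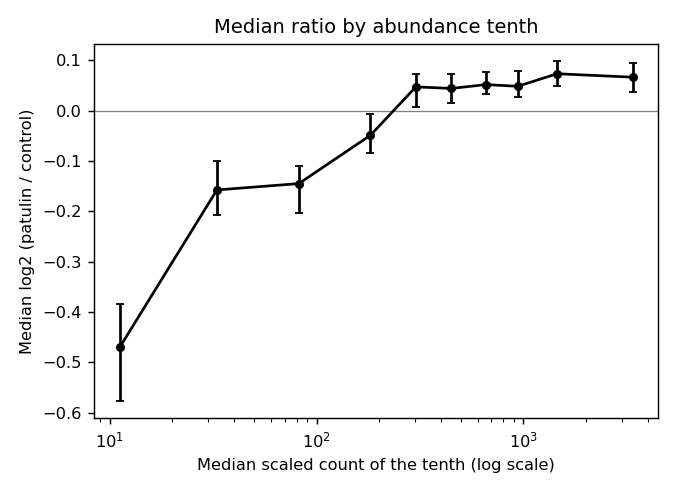
The considered genes are split into 10 parts by their mean scaled count (x axis, median of each part on a log scale), and the y axis gives the median log2 ratio, patulin over control, with bars for the 95% bootstrap interval over genes. The lowest part has a median of -0.47 and the highest one 0.07, and scaling by total counts moves the median of all genes by -0.144, which puts every part below 0. The minimum on unscaled counts is passed more easily through the deeper control, which can lower the median of the lowest parts.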

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

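Scaling by total counts gave 250 genes higher and 309 lower, against 295 and 258, so this scaling alone turned the balance between the directions. Scaling by TMM factors gave 290 and 261 and did not turn it. A minimum of 1 or 50 counts and size factors from genes with a mean scaled count of at least 100 also left both counts within 1.5 times. The pseudocount does not enter the interval, so a pseudocount of 5 counts could not move the counts. Without the interval, a ratio of at least 2-fold gave 449 higher and 603 lower genes. The same criterion on deposited values gave 559 and 776 by TPM with a pseudocount of 1, 732 and 1117 with a pseudocount of 0.1, and 475 and 809 by FPKM; these also include genes under 10 counts. A 4-fold rule gave 120 and 100. The alternatives chosen after the data were examined gave 145 and 107 components, 138 and 104 read clusters, 119 and 84 genes alone in their component, and 130 and 101 genes with whole estimated counts; all of these have fewer features to count. TRINITY_DN22_c0_g1 turned direction when its component was summed (-0.40). For the 2 named genes with counts in both libraries, 13 of 17 alternative values stayed within the counting interval and 4 lay outside it, nearer to 0. For the other 2, which have only a bound at 3 counts, 5 of 16 alternative values were nearer to 0 by more than counting error and 1 was reversed. A minimum of 1 or 50 counts does not enter the ratio of a gene. The alternative values under these minimums therefore equal the main value and could not move. Summed over components, TRINITY_DN4764_c0_g2 (-0.23) and TRINITY_DN22_c0_g2 (-0.40) no longer differed beyond 2-fold. No paired analysis was possible because each group has 1 library, and for the same reason no library could be left out. The list medians were not run because no identifier has a gene name. At these depths 88% of the genes simulated at a ratio of 0.25 were recovered, a rate that does not cover the genes of lowest count.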

Other observations

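Transcript usage was read in part from the deposited lengths, which average a gene's transcripts by their abundance. Of 348 genes with more than 1 transcript and at least 50 counts in both libraries, 20 had a mean length that differed by more than 10% between the libraries. It was longer in the patulin library for 8 of them and shorter for 12. The ratio of lengths, patulin over control, ran from 0.716 to 1.37 with a median of 0.9997. Of the 20 genes, 6 were alone in their component.

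The tests in the paragraphs that follow were in part chosen after the result was seen: those on component sums, on the other members of a component, on the thinned control, on genes alone in their component and on genes split by length for the shorter 2 of 3 length classes. The tests on components of 2 genes with nearly equal length and on all 3 length classes were set out before their results were seen.

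Among the genes past the 2-fold rule, 164 had an estimated count under 0.5 in one library. A change of the whole component is argued against for most of them. The counting interval of the component's sum lay wholly beyond 2-fold for 14 of the 164 (8.54%, exact 95% interval 4.75% to 13.9%). That exact interval treats the genes as independent. Some of them belong to the same component and so have the same sum, and the interval can be too narrow. Of the 14, 8 are the genes alone in their component, whose sum is the gene itself, and 6 are among the 156 that share one. Division of reads between near-identical assembled copies is a candidate explanation: among 46 such genes that held at least 20% of their component and were the only one of the 164 in it, the other members moved the opposite way in 37 (80.4%, 66.1% to 90.6%). With their other members replaced by those of unrelated components of similar count, under the same condition of 20%, this share averaged 54.3% over 1000 draws and reached at most 75.5%; the result is not independent of the component sums. A real switch between gene copies would give the same values and stays open. Had the strains behind the libraries differed in sequence, most components of 2 genes with nearly equal length were predicted to have each gene absent from a different library. Of 572 such components, 7 did (1.22%, exact 95% interval 0.49% to 2.5%). This share was far below that prediction, but its interval was not wholly below the limit set beforehand for arguing against a difference. The test therefore does not decide, and a difference limited to few genes stays open. The sequences that could decide were not analysed here. For the 8 genes alone in their component, an effect of the patulin culture stays open and untested.

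Low-count genes were lower in the patulin library, with a median log2 ratio of -0.47 in the lowest of 10 abundance classes of equal size and -0.16 and -0.14 in the next 2. These classes hold genes with at least 10 unscaled counts in either library. Genes near that minimum passed it more easily through the deeper control, which by itself can lower these medians. After thinning, the minimum was set on the sum of both libraries instead. Thinning the control leaves the set of assembled genes unchanged, so it cannot test whether depth decided which rare transcripts were assembled. For the counts of the assembled genes, deeper sequencing of the control is argued against as the whole cause. A gap remained with the control thinned by the scaling factor of 0.704. The 7622 genes that then had at least 10 counts over both libraries were split into 10 classes again, and the lowest 3 of these, with 2290 genes, had a median of -0.181 (95% bootstrap interval over genes -0.209 to -0.14). Division of reads between copies is argued against as well, since the 933 of these genes that were alone in their component had a median of -0.209 (-0.252 to -0.16). Gene length is argued against in the shorter 2 of 3 length classes, where the smaller of the differences between low-count and other genes was -0.245 (-0.303 to -0.175), and cannot be told apart in the longest class, where the difference of -0.157 rests on 260 low-count genes (-0.284 to -0.023). A background of reads in the control library and an effect of the patulin culture both stay open as hypotheses, since each group has 1 library.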
